A study of Mus musculus with 4 samples.

How the data were processed

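Messenger RNA was measured on 4 Affymetrix mouse arrays, one colour, with biotin-labelled RNA. The cells were hair follicle stem cells (HFSCs, the cells of the follicle that renew it during each hair cycle), sorted by flow cytometry from mouse skin at postnatal day 4, per the labels. 2 arrays carried RNA from miR-205 knockout (KO) cells and 2 from wild-type (WT) cells, and the titles number them 1 and 2 in each group as biological replicates. Groups and numbers were taken from the sample titles. The treatment text attached to all 4 samples describes a different mouse system, doxycycline induction of miR-203 in littermates, and names no miR-205 allele. It was not used to assign groups.

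The deposited table holds log2 expression values made by the authors with RMA, per the submitters' processing notes, which give no version. In general RMA corrects the background of each array, sets all arrays to 1 distribution of probe values and summarises the probes of a probe set by median polish. The values ran from 2.51 to 14.56. Array medians lay between 5.85 and 5.87. In 47.1% of the 45101 probe sets at least 2 of the 4 arrays had exactly equal values, and 366 genes had equal values within both groups. The table has no detection calls, so a dim probe set cannot be told from background and folds of dim probe sets are understated. Scan dates and the probe set definition used are not given in the sources used here. The precision is limited by the number of arrays.

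Gene names came from GEO's platform annotation, with symbols checked by gene identifier against the GRCm38.p6 RefSeq gene table, in which 34754 of the probe sets with 1 symbol matched. Of the probe sets, 34945 had 1 gene symbol, 932 had several, 9160 had none here and 64 were Affymetrix controls. Each of 18193 genes was represented by its probe set with the highest mean over the 4 arrays. No coordinates are given, since the table names no genome build.

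KO was compared with WT with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A difference is KO minus WT on the log2 scale, and its SE is the moderated standard error with 2 arrays per group. No filter on dim genes was applied. 39 gene lists were fixed before the data were examined, and 36 of them with enough measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 36 lists. For each list the number of members past the threshold was also counted adjusted over the list alone. The difference was also computed between arrays that share a number (KO 1 minus WT 1, KO 2 minus WT 2), because the numbers separated the arrays in control probe sets.

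The genes named were chosen by a rule fixed before the data were examined. It takes up to 12 genes per direction past the threshold with both KO arrays outside the WT range, ranked by size. Where fewer pass, it fills the 12 with the genes of smallest unadjusted p among those at least 1.5-fold different, above the median gene in mean level and with both KO arrays outside the WT range. It adds the 4 PI3K negative regulators of the study, the miR-205 host transcript, Zeb1, Zeb2, Cd34, Sox9, Krt14 and Krt5, and up to 4 members of smallest p per list described. Genes named outside it are marked as chosen after their values were seen.

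The fit was tested on simulated data: 20 simulations of the 18193 genes with the residual spread of the real KO and WT arrays and 200 genes changed in each. At an adjusted p under 0.05 it recovered 0.5% of genes changed 1.5-fold, 24.2% of those changed 2-fold and 56.1% of those changed 4-fold, with 0.9 unchanged genes called per simulation. A list of 20 genes shifted by 0.30 passed camera in 20 of 20 simulations, and 1 of 380 unshifted lists passed. The simulated genes were independent of one another and held no effect shared by arrays of one number, and 6.39% of unchanged genes had an unadjusted p under 0.05, against 1.88% of the real genes. These rates therefore do not carry over to the real arrays or to lists whose members move together.

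The alternatives were another normalization (quantile again, or median centring), a filter on dim genes, the mean of a gene's probe sets, every probe set by itself, a replicate block, other eBayes settings, other thresholds, other list tests, and leaving out each array. A comparison of miR-205 seed matches in 3′ UTRs had been planned and was not run, because no transcript sequence was used here.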

Results

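The study asked how gene expression in neonatal hair follicle stem cells differs when the microRNA miR-205 is missing. 4 arrays were available, 2 of KO and 2 of WT cells sorted from skin at postnatal day 4. The arrays correlated closely over all genes, with Pearson's r from 0.992 to 0.997 across the 6 pairs. Each KO array was nearer to the WT array that carries the same number (r = 0.995 for number 1 and r = 0.997 for number 2) than to the array of the other number. These correlations are across genes, which are not independent replicates. The labels call the replicates biological but do not say whether they came from separate animals or pools, so the p-values measure the spread between these samples.

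The miR-205 transcript itself was not measured. Its host transcript Mir205hg was at 6.33 ± 0.27 in KO and 5.56 ± 0.36 in WT cells (mean log2 value ± SD, n = 2 each). The difference was 0.77 with an SE of 0.26 and did not pass (limma adjusted p = 1). It was 0.71 between the number 1 arrays and 0.83 between the number 2 arrays. The Mir205hg probe set was dim, with a mean of 5.94 against 6.88 for the median gene, and the filter on dim genes removed it. The part of the locus deleted is not given in the labels, so this probe set does not check the genotype.

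Genes that mark sex separated the KO from the WT arrays and were the only genes past the threshold. Xist, the RNA that coats the inactive X chromosome, fell by 7.88 on the log2 scale in KO cells (SE 0.09, limma adjusted p = 0.038), from 13.23 ± 0.07 in WT to 5.35 ± 0.13 in KO (SD, n = 2 each). Eif2s3y, a translation initiation factor gene on the Y chromosome, rose by 6.63 (SE 0.09, limma adjusted p = 0.038), from 2.95 ± 0.14 to 9.58 ± 0.016 (SD, n = 2 each). Of the other Y-linked genes fixed beforehand, Kdm5d differed by 4.49 (limma adjusted p = 0.255, and 0.0042 with quantile normalization again or 0.045 with median centring) and Uty by 3.48 (limma adjusted p = 1). Kdm6a, an X-linked histone demethylase, differed by -0.65 (SE 0.19, limma adjusted p = 1). Every comparison of KO with WT below was therefore also a comparison of arrays that differ in Xist and Y-linked RNA. Leaving out any 1 of the 4 arrays ended both calls, with adjusted p between 0.38 and 0.86, while the differences stayed between -7.98 and -7.79 for Xist and between 6.53 and 6.73 for Eif2s3y. With the mean of a gene's probe sets Xist differed by -7.59 (adjusted p = 0.39) and Eif2s3y by 3.51 (adjusted p = 0.10), the second probe set of Eif2s3y differing by 0.39.

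**Figure D1:**
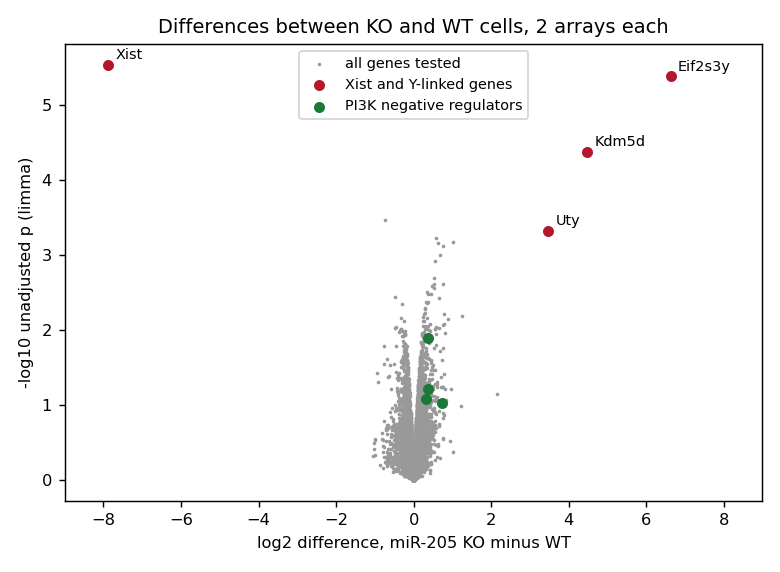
Each point is 1 of 18193 genes, with the log2 difference between KO and WT cells on the horizontal axis and the -log10 of limma's unadjusted p on the vertical axis (2 arrays per group). Xist lies at -7.88 and the 3 Y-linked genes between 3.48 and 6.63, apart from all other genes, and the 4 PI3K negative regulators lie between 0.33 and 0.74.

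Beyond these, no gene passed. Of 18193 genes tested with limma, 2 had an adjusted p under 0.05, and 342 (1.88%) had an unadjusted p under 0.05, against 910 that chance gives. Arrays of the same number deviated together (r = 0.56 across genes), and the fit holds no term for the number. The count below 910 therefore does not show that other genes are unchanged. Of the 342, 210 were higher and 132 lower in KO cells. 33 genes were also at least 1.5-fold different, 23 of them higher and 10 lower, and 29 of the 33 were outside the sex-linked list. 4 of the 29 are X-linked, Kdm6a, Bex1 (-0.92) and Nrk (-0.68) being lower and Ctps2 (0.65) higher in KO cells. The count of 33 rested on the WT arrays: it was 69 without WT 1 and 150 without WT 2, of which 122 were then lower.

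Among genes above the median level, those of smallest p that were higher in KO cells included Prdx3, a mitochondrial peroxiredoxin, at 10.50 ± 0.0015 in KO against 9.47 ± 0.11 in WT (SD, n = 2 each), a difference of 1.03 with an SE of 0.07. Krt1, the keratin of the layers above the basal epidermis, differed by 1.25 (SE 0.19). The others were the CMP-sialic acid transporter Slc35a1 (0.88, SE 0.14), the N-acetylneuraminate lyase Npl (0.79, SE 0.13), the ubiquitin ligase Mgrn1 (0.79), riboflavin kinase Rfk (0.77), the RNA-editing deaminase Apobec1 (0.76), Btbd3 (0.75), ethanolamine kinase Etnk1 (0.68), CTP synthase Ctps2 (0.65) and the Polycomb component Phc2 (0.63). The genes lower in KO cells were fewer and of larger p. They were Bcan, the proteoglycan brevican (-0.94, SE 0.27), Bex1 (-0.92, SE 0.29), the glutathione transferase Gsto1 (-0.75, SE 0.16), Kdm6a (above), the phosphatase Dusp2 (-0.63, SE 0.19) and Pid1 (-0.59, SE 0.40). The difference of Pid1 rested on WT 1, at 7.78 against 6.79 on WT 2, 6.76 on KO 1 and 6.63 on KO 2 (limma unadjusted p = 0.24). Dimmer probe sets of some of these genes disagreed, with differences of -0.11 and -0.02 for Btbd3, -0.10 to 0.49 for Etnk1, -0.10 and 0.28 for Mgrn1, 0.09 and -0.16 for Pid1 and 0.02 for 1 of the 3 others of Kdm6a. Further ones had the same sign but were smaller, at 0.30 and 0.27 for Rfk, 0.25 and 0.13 for Ctps2, -0.37 for Gsto1 and -0.16 for Bcan. Those of Phc2 (0.57) and Slc35a1 (0.69) were nearer to the values above. None of these passed the adjusted threshold, and the smallest adjusted p outside the sex-linked list was 1 (limma).

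Negative regulators of PI3K signalling were examined because the study's paper is remembered to name 4 of them as miR-205 targets. All 4 had higher values in KO cells within both numbers. Inpp4b, a lipid phosphatase, was at 6.46 ± 0.35 in KO and 5.71 ± 0.41 in WT (SD, n = 2 each), a difference of 0.74 with an SE of 0.31. Inppl1, the phosphatase SHIP2, differed by 0.38 (SE 0.13), the tyrosine kinase Frk by 0.38 (SE 0.07) and Phlda3, a protein that competes with AKT for membrane lipids, by 0.33 (SE 0.13). No member passed alone, over all genes or adjusted over the list alone, and 1 of the 4, Frk, had an unadjusted p under 0.05. As a list they rose, with a median of 0.38 (camera adjusted p = 3.0e-04, and adjusted p = 0.88 with an estimated correlation). The list did not pass without KO 2 (adjusted p = 0.17), without WT 1 (0.072) or without WT 2 (0.077). The 4 genes may have been chosen on these arrays, so their direction is not independent evidence. The second probe set of Inpp4b, a dim one at 4.33 to 4.62, differed by -0.10, and the 3 other probe sets of Frk differed by 0.05 to 0.69. 17 other negative regulators of the pathway, fixed beforehand, did not shift (median -0.03, camera adjusted p = 0.66), and neither did 19 genes of the PI3K and AKT core (median 0.02, adjusted p = 0.84) or 22 FOXO targets (median -0.05, adjusted p = 0.43).

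**Figure D2:**
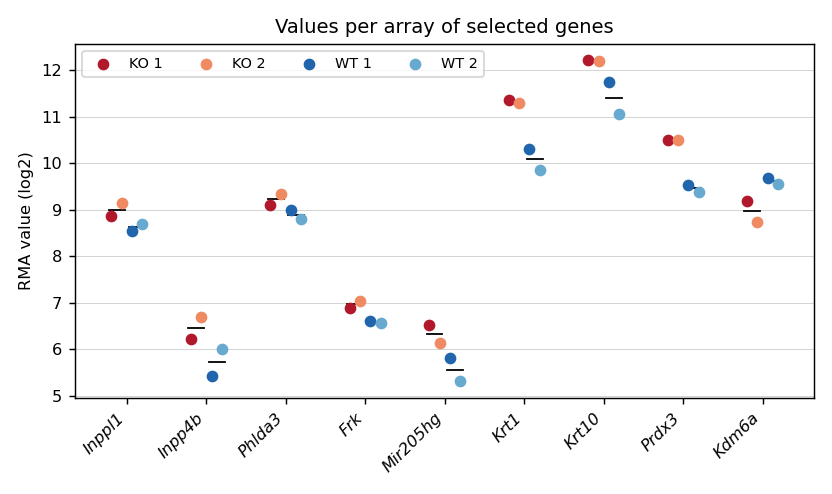
Points are RMA values (log2) of single arrays, KO 1 and KO 2 in red tones and WT 1 and WT 2 in blue tones, and each short black line is a group mean of 2 arrays. The 4 PI3K negative regulators, Mir205hg, Krt1, Krt10 and Prdx3 have both KO arrays above both WT arrays, and Kdm6a has them below. Krt1, Prdx3 and Kdm6a were named by a rule that requires this separation. Over all genes 2528 (13.9%) had both KO arrays outside the WT range, against 33.3% that chance gives for 2 against 2.

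Published targets of miR-205 did not shift as a list of 14 measured genes (median -0.01, camera adjusted p = 0.91). Erbb3, a receptor of the EGF family, differed by 0.30 (SE 0.14), Vegfa by -0.06 (SE 0.05) and the RNA helicase gene Ddx5 by -0.09 (SE 0.08). The transcription factor genes Zeb1 and Zeb2, repressors of the epithelial state, differed by -0.23 (SE 0.23) and -0.69 (SE 1.41). Because the treatment text describes miR-203 induction, targets of that microRNA were also examined. They did not shift (12 genes, median 0.07, adjusted p = 0.60), and those of smallest p went both ways. Msi2, an RNA-binding protein, differed by 0.19 (SE 0.10), the transcription factor Snai2 by 0.44 (SE 0.26), Skp2, a ubiquitin ligase subunit, by 0.26 (SE 0.16) and the growth factor Hbegf by -0.23 (SE 0.14).

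Genes of the G2 and M phases rose as a list in KO cells. The median difference of 30 genes was 0.13 (camera adjusted p = 5.1e-07, and adjusted p = 0.88 with an estimated correlation), and 28 of the 30 had higher values in KO cells, 25 of them within both numbers. The mitotic kinases Plk1 and Aurkb differed by 0.19 (SE 0.04) and 0.17 (SE 0.04), cyclin B2 (Ccnb2) by 0.24 (SE 0.10) and Ube2c, a conjugating enzyme of the anaphase-promoting complex, by 0.16 (SE 0.05). No member passed alone, over all genes or adjusted over the list alone, and Plk1 and Aurkb had an unadjusted p under 0.05. The probe set used for Aurkb had the same value, 9.17, on both WT arrays. Its second probe set differed by 0.13, with KO 2 at 8.65 below both WT arrays at 8.69. The median was 0.19 between the number 1 arrays and 0.07 between the number 2 arrays, and without KO 1 the list no longer passed (median 0.06, adjusted p = 0.052). Genes of the S phase did not shift (27 genes, median -0.02, adjusted p = 0.89), although Cdc6, a replication licensing factor, differed by 0.46 (SE 0.11) within both numbers. Clspn differed by 0.13 (SE 0.07), Mcm6 by 0.07 (SE 0.04) and Mcm3 by -0.13 (SE 0.08). CDK inhibitors and G1 cyclins had a median of -0.03 (16 genes, adjusted p = 0.89), with Cdk2 at -0.17 (SE 0.04) and Cdkn2c at 0.17 (SE 0.06).

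Basal keratinocyte genes rose as a list of 16 (median 0.12, camera adjusted p = 0.015, and adjusted p = 0.91 with an estimated correlation). The basal keratins Krt5 and Krt14 differed by 0.20 (SE 0.07) and 0.13 (SE 0.05), the laminin chain Lama3 by 0.22 (SE 0.04) and the zinc finger gene Bnc1 by 0.21 (SE 0.10). The probe set used for Lama3 had the same value, 10.31, on both WT arrays, and its other, dimmer probe set differed by -0.10. The list did not pass without KO 1 (median 0.03, adjusted p = 0.41), KO 2 (0.18, adjusted p = 0.065) or WT 2 (0.02, adjusted p = 0.57), with camera on ranks (0.062) or without genes that another list also holds (0.058). HFSC markers did not shift (18 genes, median -0.04, adjusted p = 0.89). Among them, the deiodinase Dio2 differed by 0.25 (SE 0.05), the 1 member with an unadjusted p under 0.05. Krt15, a keratin of the follicle bulge, differed by 0.24 (SE 0.12), the transcription factor Lhx2 by 0.07 (SE 0.04), the growth factor Fgf18 by -0.23 (SE 0.15), Sox9 by -0.01 (SE 0.18) and the surface marker Cd34 by -0.48 (SE 0.86). Genes of the differentiated epidermis did not pass as a list of 25 (median 0.06, adjusted p = 0.18), and passed without WT 1 (median 0.14, adjusted p = 0.0035), while without WT 2 its median was 0.0045 (adjusted p = 0.53). Krt1 is described above, and Krt10, its partner keratin, differed by 0.81 (SE 0.28), Calm4 by 0.65 (SE 0.31) and Krtdap by 0.37 (SE 0.12). Hair matrix, shaft and inner root sheath genes had a median of 0.17 and did not pass (22 genes, adjusted p = 0.11). Their median was -0.03 between the number 1 arrays and 0.34 between the number 2 arrays, and without WT 1 the list passed (median 0.35, adjusted p = 3.5e-07), while without WT 2 its median was -0.12 (adjusted p = 0.077).

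**Figure D3:**
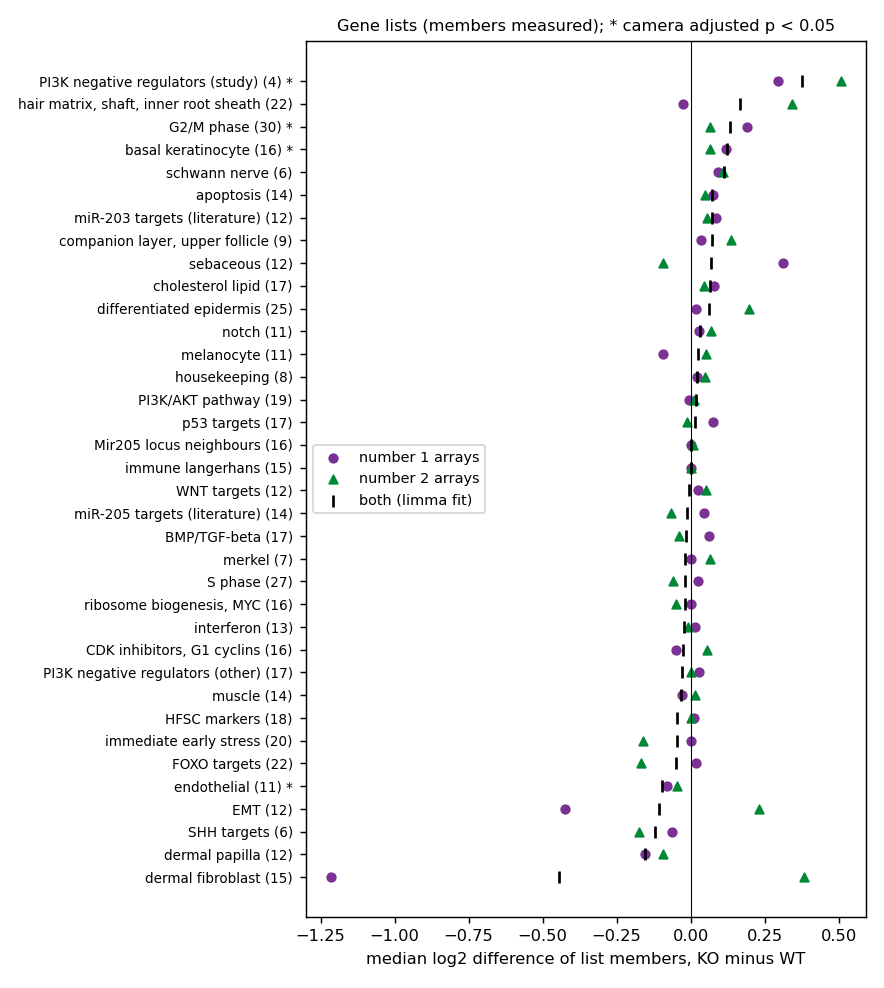
Each row is a gene list with its number of measured members, and the horizontal axis is the median log2 difference of its members between KO and WT cells. Purple circles are the number 1 arrays, green triangles the number 2 arrays, black lines the fit to all 4 arrays, and stars mark the 4 lists past camera's adjusted threshold. The dermal fibroblast list lies at -1.21 for number 1 and at 0.38 for number 2, farther apart than any other list.

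Markers of other cell types were examined because a sort can hold them. Dermal fibroblast genes differed more between single arrays than between genotypes. The median value of the 15 genes was 10.77 on WT 1, 9.22 on KO 1, 8.86 on KO 2 and 8.40 on WT 2, and 14 of the 15 were highest on WT 1 and second highest on KO 1. The fibrillar collagen gene Col1a2, chosen after its values were seen, was at 13.89, 13.10, 11.86 and 11.34 on the same arrays. Of the genes the rule names, Pdgfrb differed by -1.73 and -0.27 within the numbers, Fbln1 by 0.00 and -0.11, while Lum and Twist2 changed sign between them. The list did not pass (median -0.45, adjusted p = 0.11), and its direction depended on WT 1: without that array its median was 0.74 (adjusted p = 0.026), and without WT 2 it was -1.61 (adjusted p = 6.1e-07). With median centring it passed (adjusted p = 0.045). Cd34 and Zeb2 followed the same order of arrays, with Cd34 at 8.32 on WT 1, 6.87 on KO 1, 6.69 on KO 2 and 6.20 on WT 2. Endothelial genes fell as a list of 11 (median -0.10, adjusted p = 0.0029, and adjusted p = 0.88 with an estimated correlation), with Egfl7 at -0.28 (SE 0.08), Kdr, a VEGF receptor, at -0.24 (SE 0.09), Pecam1 at -0.10 (SE 0.05) and Esam at -0.14 (SE 0.09). The probe sets of this list are dim, with medians of 5.16 to 5.46 on single arrays, and only 3 of the 11 genes lie above the limit of the filter on dim genes, too few to test. That list did not pass without KO 1, KO 2 or WT 1 (adjusted p = 0.18, 0.17 and 0.16). Melanocyte genes did not shift (11 genes, adjusted p = 0.66), but Mitf, the transcription factor of that lineage, differed by -0.47 (SE 0.06) and was the 1 member past the threshold adjusted over the list alone. Immune (15 genes, adjusted p = 0.90), Merkel cell (7 genes, 0.97), muscle (14 genes, 0.70) and Schwann cell genes (6 genes, 0.60) did not pass.

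**Figure D4:**
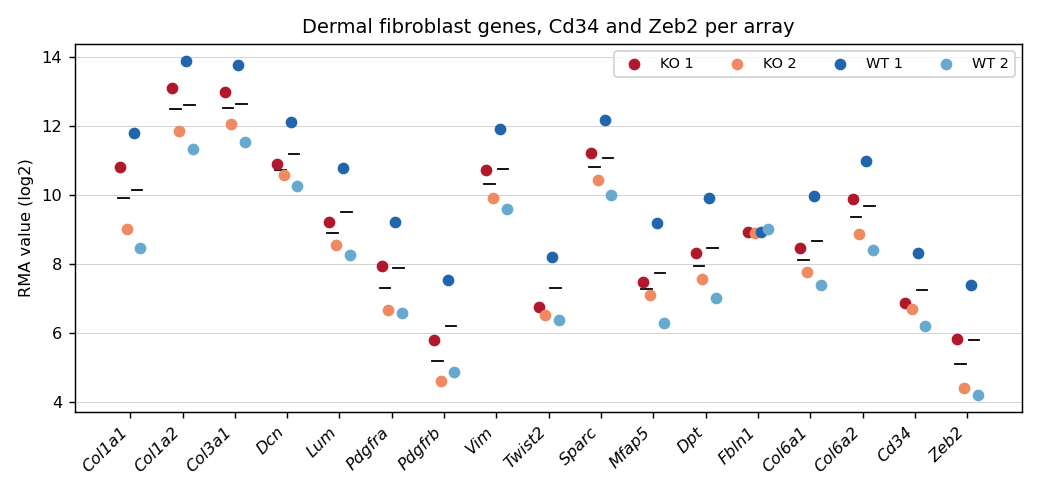
Points are RMA values (log2) of single arrays for the 15 dermal fibroblast genes and for Cd34 and Zeb2, with group means of 2 arrays as short black lines. WT 1 is the highest array for 14 of the 15 fibroblast genes and for Cd34 and Zeb2, and the group means lie between arrays that are far apart.

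Of the remaining lists none passed with camera. Dermal papilla and SHH pathway genes were nearest (12 genes, median -0.15, and 6 genes, median -0.12, both adjusted p = 0.068, and 0.042 and 0.045 with median centring), and dermal papilla genes also passed with the mean of probe sets (adjusted p = 0.017), with Fgf10, a mesenchymal growth factor, at -0.27 (SE 0.07), Fgf7 at 0.15 (SE 0.11), Rspo3 at -0.40 (SE 0.23), Hhip, of both lists, at -0.68 (SE 0.43) and the SHH receptor Ptch1 at -0.12 (SE 0.05). Of the dermal papilla genes 2 lie above the limit of the filter on dim genes, too few to test. Without single arrays the dermal papilla median ran from -0.21 (without WT 2) to -0.05 (without WT 1). The SHH median ran from -0.15 (without WT 1) to -0.05 (without WT 2). Immediate early genes, which also respond to cell dissociation, had a median of -0.05 (20 genes, adjusted p = 0.11), with Fosb at -0.49 (SE 0.13), Nr4a1 at -0.27 (SE 0.15), Jund at 0.07 (SE 0.06) and Btg2 at -0.32 (SE 0.30). That list passed without KO 1 (median -0.08, adjusted p = 0.0064) but had a median of 0.02 without KO 2 (adjusted p = 0.72), and it passed without dim genes (0.048) and with the mean of probe sets (0.041). Adjusted p was 0.27 for apoptosis genes, 0.28 for ribosome biogenesis, 0.34 for cholesterol synthesis, 0.40 for EMT genes (3.3e-04 without WT 2 with a median of -0.36, and 0.20 without WT 1 with a median of 0.43), 0.60 for interferon-responsive genes, 0.66 for companion layer and upper follicle genes, 0.71 for p53 targets and for BMP and TGF-beta genes, 0.81 for sebaceous genes, 0.86 for NOTCH and 0.89 for WNT targets. Among apoptosis genes the initiator caspase Casp8 differed by 0.56 (SE 0.15) within both numbers. Genes near Mir205 on its chromosome (16 genes, median 0.00, adjusted p = 0.97) and housekeeping genes (8 genes, median 0.02, adjusted p = 0.77) did not shift. The sign of the median differed from that of the camera test for melanocyte, Merkel cell and PI3K and AKT core genes, and from that of the mean for other negative regulators of PI3K, S phase, interferon-responsive, Merkel cell, PI3K and AKT core and Mir205 neighbour genes, with all of these medians between -0.03 and 0.03.

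Control probe sets separated the numbers and not the genotypes. The 18S ribosomal RNA probe set at the 5′ end was at 11.51 on KO 1 and 11.59 on WT 1, and at 9.46 on KO 2 and 9.40 on WT 2. The Actb value at the 3′ end minus that at the 5′ end, a sign of RNA integrity and labelling, was 0.49 ± 0.25 in KO and 0.51 ± 0.17 in WT cells (SD, n = 2 each), and 0.65 on average for number 1 against 0.35 for number 2. For Gapdh it was 0.02 ± 0.19 in KO and -0.04 ± 0.10 in WT cells (SD, n = 2 each). Between the numbers 146 genes differed at least 2-fold on average, against 12 between the genotypes. Of the 146, 51 were at least 2-fold apart the same way between KO 1 and KO 2, and 140 between WT 1 and WT 2. WT 1 was the highest array for 111 of the 146, so this count rested largely on that array.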

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

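No test in this part was planned beforehand except the fit of every probe set. 5 probe sets without a gene symbol here, which entered no comparison above, differed at least 4-fold between the groups with both KO arrays above both WT arrays. All 5 were higher in KO cells than in the WT cells that serve as the control, by 7.26, 5.78, 4.62, 2.87 and 2.28 on the log2 scale. The first was at 10.13 ± 0.16 in KO and 2.87 ± 0.10 in WT cells (SD, n = 2 each). In a limma fit of all 45037 probe sets none of them passed, where 0 probe sets had an adjusted p under 0.05 and 932 an unadjusted p under 0.05. In that fit Xist, Eif2s3y and the probe set that differed by 4.62 shared the smallest adjusted p, 0.086 (limma). High KO and low WT values are also the pattern of the Y-linked genes above. Ddx3y, a gene of the sex-linked list, had no probe set with 1 symbol here. Sex of the mice stays open for these 5 probe sets and was not tested.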

How the results depend on the processing

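The fits without sex-linked genes and without genes of 0 residual variance were chosen after the data were seen. The 2 genes past the threshold became 0 with the mean of a gene's probe sets, with every probe set tested by itself and without the sex-linked genes; leaving out single arrays gave 0 to 0. The 33 genes at least 1.5-fold different at an unadjusted p under 0.05 became 69 with every probe set, 6 at a 2-fold limit and 32 to 150 without single arrays. The 4 lists past camera's threshold became 7 with median centring, 0 with an estimated correlation, 0 with fry, 2 without genes shared between lists (basal keratinocyte genes lost their call, adjusted p = 0.058, and 2 PI3K genes were too few to test), and 1 to 5 without single arrays. With an estimated correlation all 4 lost their calls, at estimates from -0.02 (endothelial genes) to 0.57 (PI3K list). The loss was therefore not limited to lists whose members move together. The median of the PI3K negative regulators was 0.38, and its unadjusted p rose to 0.12 with an estimated correlation and to 0.074 with fry. It was 0.33 with the mean of probe sets, 0.37 with quantile normalization and 0.39 with median centring; without single arrays it ran from 0.27 to 0.48. The dermal fibroblast median ran from -1.61 to 0.74 without single arrays, the only list to change its called direction. The KO minus WT difference of the Actb 3′ and 5′ values ran from -0.20 to 0.16 without single arrays. The other settings run (quantile normalization, a filter on dim genes, other eBayes settings, camera on ranks and no genes of 0 residual variance) gave 2 or 3 genes, 30 to 47 genes and 3 or 4 lists. The filter on dim genes left 3 endothelial genes, too few to test, and immediate early genes passed with it (adjusted p = 0.048). Where a value moved, the cause was not tested, beyond that the fits without single arrays use fewer arrays. The mean of probe sets gave 25 genes at least 1.5-fold different and 6 lists. Over the alternatives the adjusted p ran from 2.9e-05 to 0.88 for the PI3K list, 1.5e-07 to 0.88 for G2/M, 0.0035 to 0.99 for basal keratinocyte, 0.0020 to 0.88 for endothelial and 6.1e-07 to 0.99 for fibroblast genes. Other eBayes settings and single probe sets were run for the PI3K genes one by one and not for their median. Arrays with the same number deviated together from their group means (r = 0.56 across genes), but the labels do not say what a number marks and there are only 2 numbers. With the replicate block 0 genes passed, 57 were at least 1.5-fold different and 9 lists passed, the further ones being hair matrix (adjusted p = 0.029), dermal fibroblast (0.021), dermal papilla (0.020), immediate early (0.011) and SHH genes (0.035), and the PI3K list median of 0.38 kept its call. Leaving out both arrays of 1 number leaves no residual degrees of freedom and so no test; a lone array is assumed to vary like the other group. The planned seed-match comparison and its alternatives were not run. The number of arrays limits all of these results, and signal over background cannot be judged without detection calls.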

Other observations

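Of the tests here, those of a wrong label, of RNA quality, of dermal cells behind the G2/M shift and of sex against genotype and the comparison of both numbers were chosen after the result was seen.

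Outside the sex-linked list, 24 genes were at least 1.5-fold different in the same direction within number 1 and within number 2, and 25 were so in opposite directions. Independent lists (350 and 193 genes) would share 1.4 in the same direction. No such value was computed for opposite directions, where 25 genes fell, so the excess over 1.4 does not set agreement apart from disagreement. Of the 25, 21 had WT 1 as the highest array and KO 1 as the second, an order that a gene higher in KO within both numbers cannot have. Of the 24, 21 were higher in KO cells, and the genes named in this paragraph were chosen after their values were seen. They held Krt1, Prdx3, Slc35a1 and Inpp4b, and further Fgf21, a metabolic hormone (1.37 and 0.59 within the numbers), the tight junction gene Cldn8 (0.85 and 0.80), the fatty aldehyde dehydrogenase Aldh3a2 (0.66 and 0.99) and H60c, a ligand of the immune receptor NKG2D in skin (0.79 and 0.72). The 3 lower genes were Bcan, Gsto1 and the imprinted noncoding RNA Snhg14 (-0.74 and -0.76). Over all genes outside the sex-linked list the differences of the 2 numbers had r = 0.04 across genes.

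For a pair of genes outside the sex-linked list, chosen after seeing the data, 1 probe set differed at least 2-fold the same way within both numbers and the others did not. For the desaturase gene Scd2, 1 probe set differed by 2.48 and 2.75 within the numbers, while the other 2 probe sets differed by -0.34 to 0.10. For the peptide transporter Slc15a2, 1 probe set differed by 1.17 and 3.11, while the other 2 differed by -0.77 to -0.11.

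The KO and WT arrays parted in Xist and Y-linked genes. A hypothesis is that the KO cells came from male and the WT cells from female mice, which the labels do not state. It predicted lower values in KO cells of X-linked genes that escape inactivation, and 5 of 5 such genes were lower within both numbers, with a median of -0.32. A wrong label was not excluded, since the within-group gaps of Xist, the larger of which was 0.19, only restate the pattern. For the 29 other genes at least 1.5-fold different, 4 of them X-linked, sex of the mice and not the genotype stays open and cannot be told apart from it, since 0 arrays part the Xist level from the genotype.

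Dermal fibroblast genes differed between arrays with WT 1 highest and KO 1 second. A hypothesis is that dermal cells or their RNA were present in the sorted cells to a different extent, the gate of the sort not being given in the labels. Of a second dermal list written without seeing its values, 11 of 13 measured genes had the same order, where chance gives 8.33%, and 1 of the 13 (Mmp2) is also an EMT list gene. That chance value treats genes as independent, while genes of the first list moved together (estimated inter-gene correlation 0.75). The order would recur in a second list under any cause that dermal genes share. Differences in RNA quality stay open for the gap between KO 1 and WT 1 (median fibroblast difference -1.21), although their Actb 3′ minus 5′ values went against them with a difference of 0.038, against 0.297 between the numbers, because the Gapdh values did not, with 0.118 against 0.205. The order was not limited to dermal genes. On WT 1, KO 1, KO 2 and WT 2 the median of hair matrix, shaft and inner root sheath genes was 8.15, 7.74, 7.69 and 7.37. That of companion layer and upper follicle genes was 9.01, 8.43, 7.89 and 7.59. Not every list had it, the basal keratinocyte median being highest on KO 1 (11.61). Other changes, specific to fibroblasts or shared with such lists, stay open.

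The G2/M list was higher on the KO arrays. A trend with expression level is argued against, because its median lay at the 100th percentile of 10000 random lists matched on mean expression. Fewer dermal cells in KO stay open: between the number 2 arrays, where fibroblast genes were higher in KO, the G2/M median was 0.07 with a bootstrap interval over members from 0.039 to 0.104, but 1 array per group holds no spread between samples. Sex of the mice and not the genotype stays open, since 0 arrays part them, and miR-205 loss stays open beside it. The list's members move together (estimated inter-gene correlation 0.17), and its call was lost with an estimated correlation (camera adjusted p = 0.88). The endothelial list lost its call there too (camera adjusted p = 0.88), with an estimated inter-gene correlation of -0.02. The loss therefore does not show that members moving together made the G2/M call.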
